A study of Homo sapiens with 14 samples.

How the data were processed

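MM1S cells, an established human myeloma line, were transduced with sub-libraries A and B of the GeCKO knockout library at a multiplicity of infection of 0.3, cultured for 2 days and selected with 1 ug/ml puromycin for 7 days, per the labels. Genomic DNA was extracted with a column kit and barcoded libraries were made by a single PCR step. The 14 samples are a baseline and vehicle and pomalidomide at days 7, 14 and 21, each from sub-library A and from sub-library B. The column names of the pomalidomide samples carry the number 100 without a unit, so the dose is not given here. The labels do not say whether samples come from separate cultures.

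The deposited tables hold raw read counts per sgRNA, made by the authors with MAGeCK (no version given in their processing notes, which also name the hg19 build). There are 3 tables, for days 7, 14 and 21, and the baseline column is the same in each. Each table stacks the 63950 sgRNAs of sub-library A and the 56869 of sub-library B, which were parted by the prefix of the sgRNA name, and each name occurs once. Each sub-library has 1000 sgRNAs named as dummy guides, called control sgRNAs here; the tables do not state what they target. Of 20699 gene names, 18803 have sgRNAs in both sub-libraries, usually 3 in each, and these were tested. The 1865 names found only in A (1795 of them microRNAs) and the 31 only in B were left out of the gene tests. Gene names are those of the tables. Compared with a RefSeq gene table of GRCh38.p14, 17289 of the 18803 are current symbols, 1340 match a single older name and 174 match none or several. No coordinates are given, since that assembly differs from the one in the processing notes.

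The sgRNA counts of a gene were summed within each sub-library, which gives 2 values per group. All 14 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM normalization), with sub-library as a block, for genes with a mean count of at least 20, a filter that removed 0 genes. The common dispersion was 0.0183, with 6 residual and 5.55 prior degrees of freedom. Log2 fold changes carry the standard error from this fit, and the values given for A and B separately use an offset of 0.5 on counts scaled to the library total (CPM). The 6 contrasts tested were pomalidomide against vehicle at each day, their mean, the difference of day 21 and day 7, and vehicle at day 21 against baseline. Genes were called at a Benjamini-Hochberg adjusted p under 0.05.

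The rank test follows the kind of gene test that MAGeCK makes and was rebuilt in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. For each day an sgRNA score was the log2 ratio of scaled counts with a pseudocount of 5, divided by the robust SD of sgRNAs of like abundance (50 bins). sgRNAs with a mean scaled count under 20 were left out. Ranks were taken within each sub-library, the aggregation used the top 0.05 of ranks, and p-values came from 100000 random sets, so that the smallest p is 1e-05. Its replicates are sgRNAs within these libraries. An sgRNA is called above the control range when its log2 ratio exceeded the 97.5th percentile of the control sgRNAs of its sub-library.

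The 17 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with fry, and on mean log2 CPM. Their p-values were adjusted over the lists within a comparison. Counts adjusted over the list alone apply the adjustment to the p-values of the list's members. The lists of NF-kB and RAS-ERK genes were written knowing the title of the series and that its paper discusses TRAF2. The lists are the CRBN ligase core, COP9 signalosome, neddylation and cullin E2 enzymes, pomalidomide neosubstrates, myeloma transcription factors and survival genes, NF-kB negative regulators and positive components, RAS-ERK positive components and negative regulators, apoptosis effectors, growth suppressors, IL6-JAK-STAT3 components, ribosomal proteins, proteasome subunits, RNA polymerase II and spliceosome core, DNA replication core and olfactory receptors.

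The groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except the thinning of all libraries to the shallowest total and the 2000000 random sets, which were added afterwards. The rule names CRBN and TRAF2 always. In the pomalidomide comparisons it adds up to 10 called genes with the largest rise and 10 with the largest fall of like sign in both sub-libraries, the 10 smallest rank p-values in each direction, the list members past either threshold outside the ribosomal, proteasome, RNA polymerase II and spliceosome, DNA replication and olfactory lists, and the 5 smallest p-values where a direction has fewer than 3 calls. In the vehicle comparison it names 10 falls, 5 rises and the 3 strongest members of each list past the threshold. The rule gave 28, 34, 43, 30, 13 and 12 genes for the 6 contrasts in that order, and the text does not name every one of them. Other genes (COPS3, COPS5, CUL4A, CUL4B, IKZF1, IKZF3, IRF4, SNRPG, NAE1 and UBE2M at day 14, and those of the closing section) were chosen after their values were seen.

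Alternatives were median-ratio size factors, total count and control sgRNA scaling, no filter or a mean count of at least 100, no replicate block, the libraries of a comparison alone, DESeq2 1.42.0, limma-trend on the mean log2 CPM of the sgRNAs of a gene, sums without the most abundant sgRNA of each gene and sub-library, and each library left out in turn. For the rank test they were each sub-library alone, a pseudocount of 1, no abundance filter or a minimum of 50, percentiles among control sgRNAs, and the plain log2 ratio. Both tests were tested on simulated data at day 21, in which 50 of the 18803 genes were changed by each of 4 known folds. edgeR recovered 7 of 50 at a fold of 1.5, 36 at 2, 50 at 4 and 36 at 0.5, with 8 false calls, and the rank test 16, 42, 48 and 45 with 2 false calls when 70% of sgRNAs were active. The simulation has no chance growth of single clones. For the rank test its sgRNA spread came from the day 7 libraries, and for edgeR from all 14 libraries. Control sgRNAs of sub-library A had an SD of log2 ratios of 0.378 at day 7 and 0.728 at day 21. The recoveries may thus be too high, and the false calls too few, for day 21.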

Results

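The screen counted single guide RNAs (sgRNAs) in genomic DNA of MM1S, a human myeloma cell line, after knockout with the genome-wide GeCKO library. It asked which gene losses change how cells fare under pomalidomide, a drug that binds cereblon, the product of CRBN, and redirects its ubiquitin ligase. The labels give 7 groups: a baseline, and vehicle and pomalidomide at days 7, 14 and 21. Each group has 2 samples, from sub-library A and from sub-library B, which carry different sgRNAs against the same genes, so a gene has 2 values per group. Total counts were 14157828 to 16757306 per library in sub-library A. In sub-library B they were 46897891 to 55784744, except 21696987 for vehicle at day 21. The median count per sgRNA was 187 to 207 in A, 667 to 778 in B, and 301 in that shallower library. Between 0.026% and 0.205% of sgRNAs had a count of 0. The labels do not state that the samples are separate cultures, so p-values here measure the spread between these samples. A gene is said to rise or fall when the summed counts of its sgRNAs did so past the test's threshold.

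CRBN sgRNAs accumulated under pomalidomide in both sub-libraries. They made up 1.74% of the counts of pomalidomide at day 21 in sub-library A (Wilson 95% interval 1.74% to 1.75%) against 0.0034% (0.0031% to 0.0037%) in vehicle. In sub-library B the shares were 0.401% (0.399% to 0.403%) and 0.0021% (0.0019% to 0.0023%). At day 14 the pomalidomide shares were 0.171% in A and 0.0654% in B, and at day 7 they were 0.0108% and 0.0066%. The baseline shares were 0.0049% in A and 0.0028% in B. These intervals cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The mean log2 ratio of pomalidomide over vehicle across the CRBN sgRNAs was 1.34 ± 0.70 at day 7, 5.21 ± 1.09 at day 14 and 8.12 ± 1.40 at day 21 (SD, n = 6 sgRNAs). At day 7, 5 of the 6 sgRNAs lay above the central 95% of control sgRNAs, and at days 14 and 21 all 6 did.

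**Figure D1:**
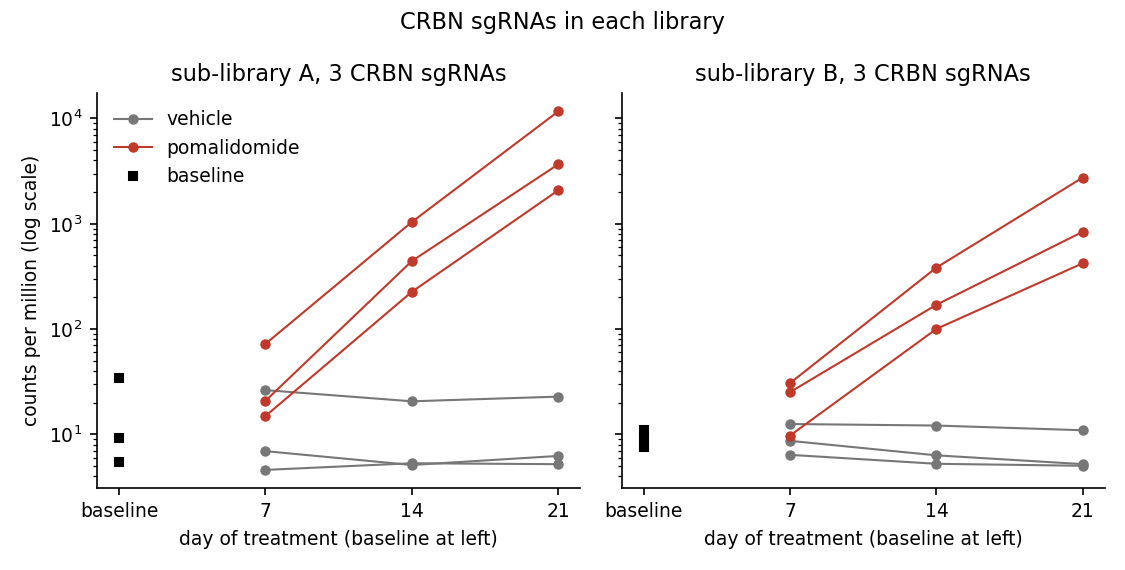
Scaled counts (CPM) of each CRBN sgRNA (log scale) against the day of treatment, with a line per sgRNA in vehicle (grey) and pomalidomide (red), squares for the baseline and a panel per sub-library. In pomalidomide all 6 sgRNAs climb, and the mean log2 ratio over vehicle is 8.12 at day 21.

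Day 7 asked which knockouts responded early. CRBN had a log2 fold change of 1.37 ± 0.32 (SE, n = 2 libraries per group). MYC, a transcription factor that myeloma cells depend on, stood at 0.99 ± 0.17, and its sgRNAs also fell in vehicle by day 21. Neither passed the adjustment in edgeR (adjusted p = 0.9999 for both). In the sgRNA rank test both reached the smallest p that the random sets can give, 1e-05, with an adjusted p of 0.0940. TRAF2, an adaptor of TNF receptor signalling that restrains the NF-kB-inducing kinase, stood at 0.48 ± 0.53. PEX5L stood at 0.91, GMPPB at 1.10, MRP63 at 0.78, SPTLC2 at 0.72, NAA10 at 0.60, UBE2G1 at 0.45, COPS6 at 0.45 and NAA25 at 0.41. On the falling side TMEM82 stood at -0.50, MAB21L3 at -0.56, CATSPER1 at -0.69, RCHY1 at -0.86 and CD248 at -0.32. edgeR called 0 of 18803 genes, with 340 at an unadjusted p under 0.05 (189 positive and 151 negative). DESeq2 called 2 genes and the rank test 0, with 973 genes at an unadjusted p under 0.05 for a rise and 914 for a fall. With the 4 libraries of the comparison alone edgeR called 7 genes, and the rank test called 3 with 2000000 random sets and 4 against the control sgRNAs. The main edgeR fit shares its spread over all 14 libraries, and control sgRNAs varied less at day 7 than at day 21. Its day 7 p-values may thus be too large.

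As groups, 3 of the 17 fixed lists shifted upward at day 7. The COP9 signalosome, the complex that removes NEDD8 from cullins, had a median of 0.32, with 8 of 9 members positive and camera adjusted p = 0.00129. The CRBN ligase core, which holds CRBN, the adaptor DDB1, the cullins CUL4A and CUL4B and the RING protein RBX1, had a median of 0.13 (adjusted p = 5.68e-04), and adjusted over the list alone 2 of its 5 members rose. Ribosomal proteins had a median of 0.11, with 60 of 76 positive (adjusted p = 1.48e-04). No member of the COP9 or ribosomal list rose when adjusted over the list alone (0 of each), and 0 members of any list passed over all genes. All 3 calls held with an estimated correlation, with adjusted p = 0.0490 for COP9 and the CRBN core and 0.0349 for ribosomal proteins, and the CRBN core was lost on mean log2 CPM (adjusted p = 0.133).

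By day 14, 4 genes rose under pomalidomide. CRBN rose 38.6-fold (log2 5.27 ± 0.38, adjusted p = 2.75e-04), followed by PCBP2, a poly(C) RNA-binding protein, at 1.71 ± 0.16 (adjusted p = 0.00170). EDC4, a scaffold of mRNA decapping, rose by 1.62 ± 0.19 (adjusted p = 0.0139), and GNB2L1, now RACK1, a scaffold on the small ribosomal subunit, by 1.13 ± 0.12 (adjusted p = 0.00508). edgeR called 0 falls, with 382 genes negative at an unadjusted p under 0.05, while DESeq2 called 24 rises and 2 falls and the rank test 40 rises and 0 falls. Without the sub-library block edgeR called 0 genes, and with the 4 libraries alone 12. Leaving out vehicle A or vehicle B left 1 call and leaving out pomalidomide A left 2, and without the most abundant sgRNA of each gene PCBP2 was at 0.94 and EDC4 at 0.97.

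The rank test, which asks whether several sgRNAs of a gene sit near the top, included those 4 genes among its 40 rises at day 14. Its strongest calls, at the smallest p of 1e-05 (adjusted p = 0.00855), also held COPS7B (log2 2.06 ± 0.41), MRP63, now MRPL57, a mitochondrial ribosomal protein (1.64 ± 0.23), the co-repressor NCOR1 (1.66 ± 0.42), COPS7A (0.93 ± 0.18), the stimulatory G protein subunit GNAS (0.96 ± 0.15), the cullin adaptor SPOP (1.30 ± 0.37) and the start-codon factor EIF1 (1.19 ± 0.41). edgeR did not call these, with adjusted p from 0.0670 for MRP63 to 0.9999 for SPOP and EIF1. TRAF2 was called by ranks (adjusted p = 0.00855) with 4 of 6 sgRNAs above the control range, but not by edgeR, where it stood at 1.36 ± 0.54 (adjusted p = 0.9999) with 0.19 in sub-library A and 2.34 in B. MYC was also called by ranks, at 1.00 ± 0.17 with 5 of 6 sgRNAs above the control range. MYC and MRP63 were also among the 10 genes called as falls in vehicle from baseline to day 21. For these genes protection from the drug and growth cost of the knockout cannot be told apart here. UBE2G1, a ubiquitin-conjugating enzyme that works with cullin ligases, stood at 1.59 with 0.08 in A and 2.78 in B, and ARID2, a PBAF chromatin remodelling subunit, at 0.87 with -0.25 in A and 1.68 in B. TNFRSF13B, a receptor for the survival factors BAFF and APRIL, was called at 0.68 ± 0.23 (adjusted p = 0.0294). MAP3K8 (-0.76), DDX26B (-1.30), CDH13 (-0.89) and TNNI3 (-0.77) had among the lowest rank p-values for a fall, and none was called. Sub-library A alone gave 5 rank calls and B alone 17, and TRAF2 in A alone had adjusted p = 0.844, while ranking against the control sgRNAs gave 87.

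Of the fixed lists, 6 shifted upward at day 14. COP9 signalosome members had a median of 0.87, with 9 of 9 positive, 0 past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 1.21e-21), and the rank test called COPS7B, COPS7A, COPS2 and COPS4. In the CRBN ligase core 1 of 5 rose over all genes and 2 adjusted over the list alone (median 0.49, adjusted p = 1.24e-14), and DDB1 stood at 0.86 ± 0.15. Its median was -0.05 in sub-library A and 0.57 in B. Neddylation and cullin E2 enzymes had a median of 0.21, with 0 of 16 over all genes and 3 adjusted over the list alone (adjusted p = 2.77e-08), which were NAE1 (0.90), a subunit of the NEDD8-activating enzyme, UBE2M (0.69), the NEDD8-conjugating enzyme, and CAND1 (0.87), the cullin exchange factor. NF-kB negative regulators had a median of 0.15 (adjusted p = 0.00102), with 9 of 10 positive, 0 over all genes and 1 adjusted over the list alone. That list was written knowing the title of the series and that TRAF2 features in its paper, so it is not independent evidence. Ribosomal proteins had a median of 0.12 with 60 of 76 positive (adjusted p = 3.06e-04) and 0 members past either adjustment. Myeloma transcription factors and survival genes had a median of 0.09 (adjusted p = 0.0158), with 2 of 16 adjusted over the list alone and 0 over all genes, and adjusted p = 0.170 with an estimated correlation. The other 5 calls held with an estimated correlation, at larger adjusted p, from 8.57e-04 for COP9 to 0.0314 for NF-kB negative regulators.

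At day 21 edgeR called 152 rises and 27 falls, with 3530 genes at an unadjusted p under 0.05. These calls use a spread shared over all 14 libraries, and with the 4 libraries of day 21 alone edgeR called 0 genes. Control sgRNAs varied more at day 21 than at day 7. The SD of their log2 ratios was 0.728 against 0.378 in sub-library A, and 0.555 against 0.349 in B. The p-values of day 21 may thus be too small, and those of days 7 and 14 too large. In sub-library A the SD at day 14 was 0.45. The few edgeR calls at days 7 and 14 do not show that early effects were absent. CRBN and COPS7B, of the cullin ligase machinery, had the largest rises. CRBN rose 356-fold (log2 8.47 ± 0.44, adjusted p = 6.97e-06), COPS7B by 3.92 ± 0.44 (adjusted p = 0.00287), DDB1 by 2.27 ± 0.15 (adjusted p = 5.23e-05), COPS8 by 2.23 ± 0.19 and COPS7A by 2.22 ± 0.19 (adjusted p = 2.41e-04 for both). Outside those complexes the largest rises were NCOR1 at 2.93 ± 0.45, EDC4 at 2.86 ± 0.20, PLAA, a ubiquitin-binding partner of the VCP segregase, at 2.64 ± 0.27, SPOP at 2.40 ± 0.39 and the olfactory receptor OR4C11 at 2.18 ± 0.44. OR4C11 rested on 2 of its 6 sgRNAs and stood at 0.02 without the most abundant sgRNA of each sub-library. GNAS rose by 1.81 ± 0.15. Falls were smaller: PARP16 changed by -1.02 ± 0.20, the neuronal chloride transporter SLC12A5 by -0.98 ± 0.15, the pseudophosphatase STYX by -0.98 ± 0.15, KIAA0408 by -0.91, SV2C by -0.90, SEP15, now SELENOF, by -0.89, PABPC5 by -0.82, TSSK1B by -0.81, the co-repressor BCORL1 by -0.80 and CCDC19 by -0.79. Every called gene had the same sign in A and B (179 of 179), which a call nearly requires, so it is not independent support. Over all genes the correlation of the A and B fold changes was 0.034 at day 7, 0.103 at day 14 and 0.075 at day 21. Of the 152 risen genes, 25 had 3 or more sgRNAs above the central 95% of control sgRNAs and 127 had 2 or fewer.

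TRAF2 stood at 2.49 ± 0.56 at day 21, short of the edgeR threshold (adjusted p = 0.0652) and past that of the rank test (adjusted p = 0.0145). Its log2 fold change was 1.08 in sub-library A and 3.61 in B. The 3 sgRNAs of B had log2 ratios of 5.73, 1.75 and 2.70, while in A 1 sgRNA had 4.16 and the others -0.08 and -0.16. In sub-library A alone the rank test gave TRAF2 adjusted p = 0.569. The rank test called 19 rises and 0 falls at day 21, with 972 and 950 genes at an unadjusted p under 0.05. Of the 19 rises, edgeR, run on the same counts, also called 15. The other 4 were TRAF2, UBE2G1 (2.76 ± 0.71, with 1.00 in A and 3.95 in B), ARID2 (1.27 ± 0.61, with -0.39 in A and 2.58 in B) and LZTR1, a cullin adaptor that targets RAS proteins (1.28 ± 0.33). Days 14 and 21 shared 16 rank-called genes, which clones carried from day to day would also give. Sub-library A alone gave 0 rank calls at day 21 and B alone 4. In A alone CRBN itself had adjusted p = 0.0627 at the smallest p of 1e-05, so the number of random sets can hold back calls there. More random sets were not tried in A alone.

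**Figure D2:**
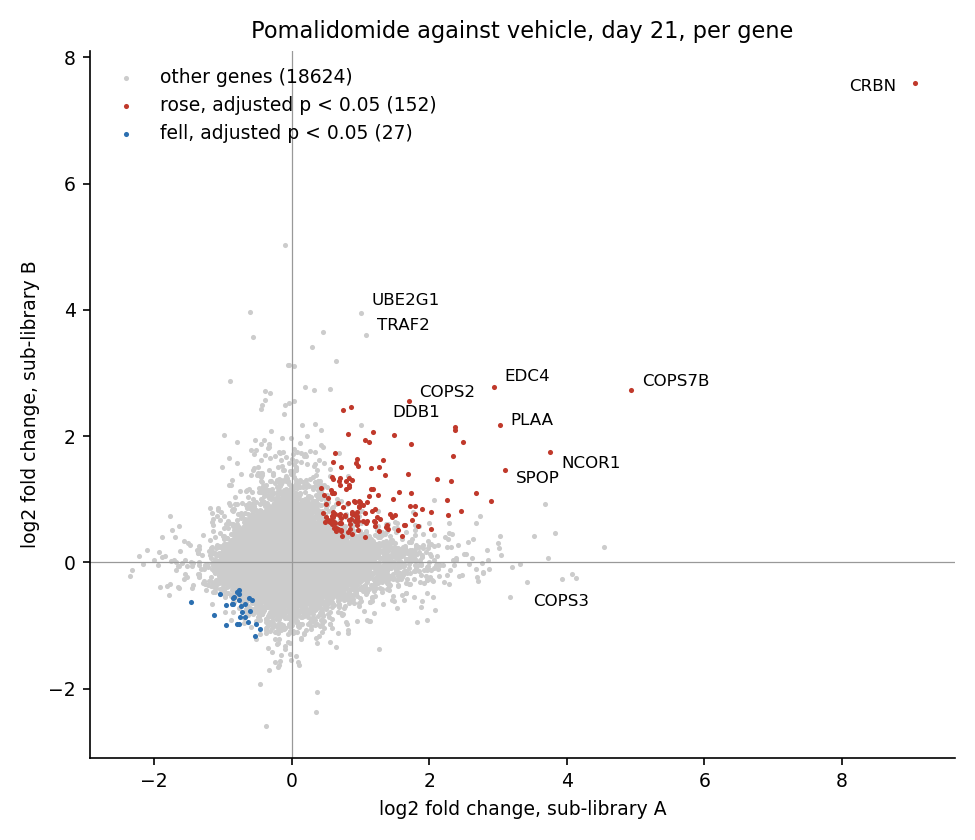
Log2 fold change of pomalidomide over vehicle at day 21 in sub-library A (x axis) against sub-library B (y axis), with a point per gene, red for the 152 that rose and blue for the 27 that fell in edgeR. CRBN lies at 9.07 in A and 7.60 in B, and TRAF2 at 1.08 and 3.61.

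Of the fixed lists, 5 shifted upward at day 21, and 16 of the 152 risen genes belong to any list. All 9 COP9 signalosome members were positive (median 2.17), 7 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 2.02e-35). COPS2 rose by 2.17 ± 0.27, COPS4 by 1.82 ± 0.21, COPS6 by 1.26 ± 0.18 and GPS1 by 0.98 ± 0.19, while COPS3 at 2.37 (3.93 in A and -0.27 in B) and COPS5 at 1.72 (0.32 in A and 2.73 in B) missed the threshold over all genes. In the CRBN ligase core CRBN and DDB1 rose, 2 of 5 over all genes and 3 adjusted over the list alone (adjusted p = 1.52e-19). CUL4B stood at 1.09 and CUL4A at 0.05, and the list's median was 1.09, with 0.18 in A and 1.68 in B, the values of CUL4B. CAND1 rose by 1.75 ± 0.21 and was the single edgeR call among 16 neddylation and cullin E2 genes, with 6 adjusted over the list alone (median 0.39, camera adjusted p = 9.23e-05). The rank test called 2 of the 16, CAND1 and UBE2G1 (adjusted p = 0.0145 for both). Among NF-kB negative regulators NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, rose by 1.02 ± 0.16 and the ubiquitin ligase BIRC3 by 0.63 ± 0.12, 2 of 10 over all genes and 3 adjusted over the list alone (median 0.35, adjusted p = 4.22e-04). Neither was called by the rank test (adjusted p = 0.662 for NFKBIA with 2 of 6 sgRNAs above the control range, and 0.9998 for BIRC3 with 0 of 6). BIRC3 lost its call under total count scaling and under control sgRNA scaling, and the caution on the origin of this list applies here too. In growth suppressors DEPDC5, a GATOR1 subunit that restrains mTORC1, rose by 1.36 ± 0.20, 1 of 20 over all genes and 3 adjusted over the list alone (median 0.12, adjusted p = 0.0311), with adjusted p = 0.100 with an estimated correlation. The other 4 list calls held with an estimated correlation, at larger adjusted p, from 2.01e-04 for COP9 to 0.0281 for NF-kB negative regulators.

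The remaining lists did not shift at day 21. Neosubstrates, the proteins that pomalidomide brings to CRBN, had a median of 0.06 and a mean of 0.07 with a downward camera direction (adjusted p = 0.980), and 0 of 13 passed either adjustment in edgeR, while the rank test called ARID2 (adjusted p = 0.0145). IKZF1 stood at 0.10 and IKZF3 at 0.06. RAS-ERK negative regulators had a median of 0.16 (adjusted p = 0.980), with 0 of 18 over all genes, and 2 rises and 3 falls adjusted over the list alone, and the rank test called LZTR1 (adjusted p = 0.0442). RAS-ERK positive components had a median of -0.06 and a mean of 0.03 (adjusted p = 0.980), with 0 of 17 over all genes and 1 fall adjusted over the list alone. Both RAS-ERK lists were written knowing the series title and are not independent of it. NF-kB positive components had a median of -0.02 and a mean of 0.06 (adjusted p = 0.980), with 1 of 18 risen adjusted over the list alone. Apoptosis effectors stood at a median of -0.04 (adjusted p = 0.980), IL6-JAK-STAT3 components at 0.09 (adjusted p = 0.815) and myeloma transcription factors at -0.02 (adjusted p = 0.980), each with 0 members past either adjustment. Ribosomal proteins were at 0.05 (adjusted p = 0.392), proteasome subunits at 0.05 (adjusted p = 0.944), RNA polymerase II and spliceosome genes at 0.04 (adjusted p = 0.980) and DNA replication genes at 0.01 (adjusted p = 0.980). SNRPG, a spliceosome protein, fell by 0.72. Olfactory receptors, which myeloma cells are not known to use, had a median of -0.01 (adjusted p = 0.980), with 3 of 371 risen over all genes and 4 adjusted over the list alone.

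**Figure D3:**
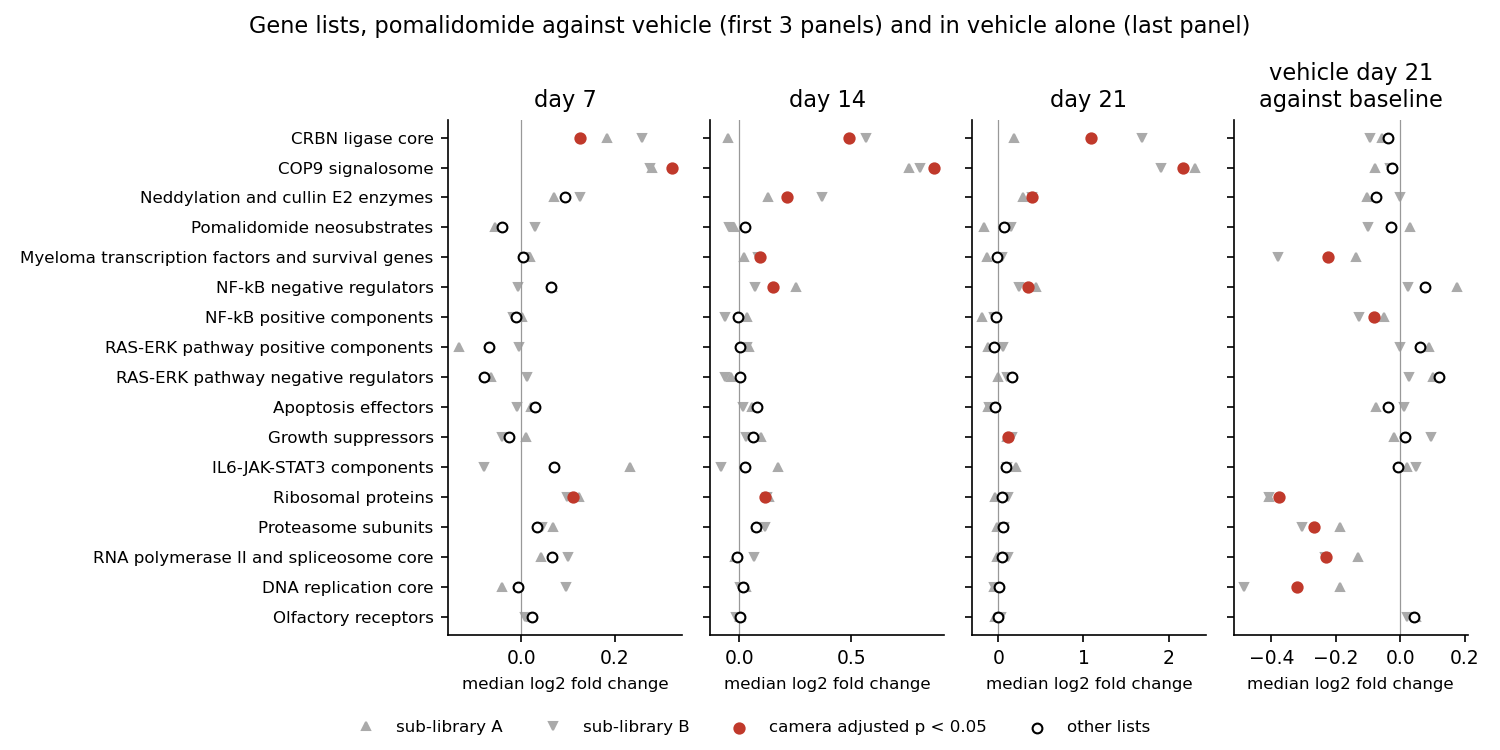
Median log2 fold change of each fixed gene list (circles, filled red where camera adjusted p was under 0.05; triangles, sub-libraries A and B) for pomalidomide over vehicle at each day and for vehicle at day 21 over baseline, in panels with different x ranges. The COP9 signalosome median moves from 0.32 at day 7 to 0.87 at day 14 and 2.17 at day 21.

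At day 21 edgeR called 0 genes without the sub-library block and 0 with the 4 libraries alone, DESeq2 988 (629 rises and 359 falls), and edgeR 51 without the most abundant sgRNA (49 rises and 2 falls). Leaving out vehicle A gave 39 rises and 57 falls, with 44 of the 96 among the 179. Leaving out vehicle B gave 17 rises and 7 falls, pomalidomide A 871 and 179, and pomalidomide B 2028 and 741. Total count scaling gave 97 rises and 73 falls, and NCOR1 and SPOP lost their calls without vehicle A or vehicle B. CRBN, COPS7B, EDC4, PLAA, DDB1 and COPS7A kept theirs in every setting except without the block and with the 4 libraries alone.

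The mean over the 3 days asked which knockouts differed on average, not at each day, with 6 pomalidomide and 6 vehicle libraries. These come from the pools of sub-libraries A and B, and the labels do not say that the days are separate cultures. The fit treats the days as separate samples, so its standard errors and p-values may be too small. CRBN rose by 5.04 ± 0.22 (adjusted p = 9.13e-07), COPS7B by 2.13 ± 0.24, EDC4 by 1.69 ± 0.11, PLAA by 1.55 ± 0.15, NCOR1 by 1.55 ± 0.25 (0.06 at day 7), PCBP2 by 1.41 ± 0.09, SPOP by 1.27 ± 0.22, COPS2 by 1.25 ± 0.15, MRP63 by 1.20 ± 0.13 and DDB1 by 1.20 ± 0.08. MYC rose by 0.86 ± 0.10 (adjusted p = 0.00244), CAND1 by 0.95 ± 0.12, UBE2M by 0.55 ± 0.10, NAE1 by 0.54 ± 0.08 and NFKBIA by 0.51 ± 0.09. MYC and MRP63 were also called as falls in vehicle from baseline to day 21. TRAF2 stood at 1.44 ± 0.32 (adjusted p = 0.0906). Falls were below 1 log2 unit, from RNF135 at -0.63 ± 0.11 and NCOA7 at -0.58 ± 0.09 through STYX (-0.56), RANBP17 (-0.53), the bitter taste receptor TAS2R5 (-0.49), TSSK1B (-0.47), SEP15 (-0.46), MEIS1 (-0.42) and IPO4 (-0.42) to WDR13 (-0.40). In all, 62 genes rose and 12 fell. The number of falls depended on the setting, with 4 for the 12 libraries alone, 3 without the most abundant sgRNA and 26 with limma-trend in place of edgeR. The lists called were the CRBN core (2 of 5 over all genes, 3 adjusted over the list alone, adjusted p = 3.15e-25), COP9 (6 of 9 and 9 adjusted over the list alone, 1.79e-37), neddylation (3 of 16 and 7, 7.67e-08), NF-kB negative regulators (1 of 10 and 3, 4.73e-04) and ribosomal proteins (0 of 76 by either adjustment, 4.73e-04). All 5 held with an estimated correlation, at larger adjusted p, from 1.7e-04 for COP9 to 0.0237 for NF-kB negative regulators. edgeR called 0 genes without the block, 48 with the 12 libraries alone, 35 without the most abundant sgRNA and 20 to 26 without any 1 library of day 7 or 14, while DESeq2 called 533 (303 rises and 230 falls). Leaving out a day 21 library gave 58 for vehicle A, 38 for vehicle B, 821 for pomalidomide A and 1862 for pomalidomide B.

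The difference between days asked whether the pomalidomide effect was larger at day 21 than at day 7, as a test of that difference. It was for 7 genes: CRBN by 7.11 ± 0.50 (adjusted p = 2.00e-04), EDC4 by 2.28 ± 0.27, COPS7A by 2.11 ± 0.26, COPS8 by 1.88 ± 0.26, DDB1 by 1.81 ± 0.21, the chromatin remodeller HELLS by 1.68 ± 0.19 and PCBP2 by 1.54 ± 0.22. TRAF2 differed by 2.00 ± 0.75, which did not pass (adjusted p = 0.581). Each effect is the log2 ratio of counts reached by that day, so a steady growth advantage would also give a larger value at day 21. edgeR called 0 genes with a smaller effect at day 21, with 688 negative at an unadjusted p under 0.05 and 18 called by DESeq2; the smallest p-values belonged to ACD (-1.002), PABPC5 (-1.02), KIAA0408 (-0.96), EDEM2 (-0.77) and ST3GAL6 (-1.13). The CRBN core (median 1.02, with 0.00 in A and 1.72 in B; 2 of 5 over all genes and adjusted over the list alone, adjusted p = 6.65e-17), COP9 (2 of 9, and 8 adjusted over the list alone, 3.25e-26) and NF-kB negative regulators (0 of 10, and 1 adjusted over the list alone, 0.00146) shifted upward. With an estimated correlation their adjusted p was 0.00103, 4.89e-04 and 0.0499 in that order. Neddylation (0 of 16, and 1 adjusted over the list alone, 0.0124) had adjusted p = 0.0799 with an estimated correlation and growth suppressors (0 of 20, and 1, 0.0243) adjusted p = 0.0888. HELLS turned to -0.20 without the most abundant sgRNA, a setting that left 3 calls, and edgeR called 0 genes without the block, 1 with the libraries of the comparison alone and 4 with limma-trend in its place, against 103 by DESeq2. Leaving out vehicle A or B of day 7 left 1, pomalidomide A or B of day 7 left 2 and vehicle B of day 21 left 4, while leaving out vehicle A of day 21 gave 3 rises and 7 falls and the pomalidomide libraries of day 21 gave 359 for A and 1307 for B.

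Vehicle at day 21 against baseline asked which knockouts were lost during growth without drug. Every one of the 10 called genes fell: MRP63 by 1.93 ± 0.24, PDCD2, a ribosome assembly factor, by 1.70 ± 0.15 (adjusted p = 0.00118), TRMT112, a partner of several methyltransferases, by 1.54 ± 0.16, the histone gene HIST2H4A by 1.52 ± 0.13, the mitochondrial phosphatase PTPMT1 by 1.43 ± 0.17, the ribosomal protein gene RPL3 by 1.34 ± 0.16, MYC by 1.22 ± 0.17 (adjusted p = 0.0272), NFKB2, a subunit of noncanonical NF-kB, by 1.15 ± 0.14, SRM, spermidine synthase, by 1.10 ± 0.14 and MSTO1 by 1.03 ± 0.15. CRBN stood at -0.43 ± 0.32 and TRAF2 at 0.06 ± 0.53, neither called. edgeR called 0 rises, with 684 genes positive at an unadjusted p under 0.05 and 31 rises by DESeq2. Ribosomal proteins shifted down as a list (median -0.38, 1 of 76 fell over all genes and 21 adjusted over the list alone, adjusted p = 3.77e-30), as did DNA replication genes (-0.32, 0 of 26 and 6, 2.13e-08), proteasome subunits (-0.27, 0 of 32 and 2, 2.13e-08) and RNA polymerase II and spliceosome genes (-0.23, 0 of 34 and 3, 4.84e-07). With an estimated correlation the adjusted p of these lists ran from 1.8e-04 for ribosomal proteins to 0.00938 for RNA polymerase II and spliceosome genes. Myeloma transcription factors and survival genes also shifted down (-0.23, 1 of 16 over all genes and 4 adjusted over the list alone, adjusted p = 7.04e-07), and IRF4, the lineage factor of myeloma, stood at -1.06 ± 0.18 (adjusted p = 0.0876). NF-kB positive components had a median of -0.08 (1 of 18 and 2, adjusted p = 0.0172), with adjusted p = 0.0607 with an estimated correlation, while olfactory receptors stood at 0.04 (adjusted p = 0.221, and 0.0309 upward with an estimated correlation). Scaling to control sgRNAs moved the median of all genes from 0.01 to -0.16 and gave 124 falls, and edgeR called 0 genes without the block and 58 (5 rises and 53 falls) with the 4 libraries alone, against 95 by limma-trend and 188 by DESeq2. Leaving out either baseline left 6 and vehicle B 2, while leaving out vehicle A gave 22 rises and 6 falls.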

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

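The difference between days was a planned test, while the comparison of microRNAs with sets of control sgRNAs was set up after the tables had been seen. Pomalidomide effects were larger at day 21 than at day 7 for 7 genes by the edgeR test of the difference itself. The difference was 7.11 on the log2 scale for CRBN (effect 1.37 at day 7 and 8.47 at day 21). It was 2.28 for EDC4, 2.11 for COPS7A, 1.88 for COPS8, 1.81 for DDB1, 1.68 for HELLS and 1.54 for PCBP2, each of the same sign in both sub-libraries. A call nearly requires such agreement. HELLS stood at -0.20 when the most abundant sgRNA of each sub-library was left out, and without 1 library the count of 7 genes ranged from 1 to 1307. Each effect is the log2 ratio of counts reached by that day, so a steady growth advantage would also widen it from day 7 to day 21. The test thus does not show that the effect of the drug itself grew. No technical or biological explanation of these differences was tested.

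MicroRNA genes have sgRNAs in sub-library A only and take part in none of the gene tests. At day 14, 2 of 1333 microRNAs with 4 sgRNAs had a median log2 ratio of pomalidomide over vehicle above the highest of 10000 random sets of 4 control sgRNAs, 0.90 (0.8965 before rounding). They were hsa-mir-3687 at 1.23 and hsa-mir-3156-1 at 0.90 (0.9048 before rounding). At day 7, 0 of 1344 and at day 21, 0 of 1309 lay above or below all control sets. If microRNA sgRNAs varied like control sgRNAs, 0.133 of the 1333 would lie above all sets by chance. The 4 sgRNAs of a microRNA come from the same pool of cells, sub-library B holds none, and the cause of these 2 values was not tested.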

How the results depend on the processing

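Thinning to the shallowest library and the 2000000 random sets were chosen after the data were seen; the other alternatives were planned, and the cause was not tested for the changes below. Median-ratio size factors, both filters and thinning kept each edgeR count of changed genes within 1.5 times its value, but these filters nearly change nothing, since the filter used removed 0 genes. Total count scaling did too, but its day 21 calls split into 97 rises and 73 falls (57.1% rises against 84.9%) and share 124 of 179 genes with the calls reported. Control sgRNA scaling, which moved the median of all genes in vehicle from 0.01 to -0.16, gave 124 genes there. With no replicate block, the pairing by sub-library is lost and edgeR called 0 genes at days 14 and 21, in the mean, in the difference and in vehicle (42, 378, 248, 85 and 93 at an unadjusted p under 0.05). With the libraries of the comparison alone it called 7 at day 7, 12 at day 14, 0 at day 21 (829 unadjusted), 48 in the mean, 1 in the difference and 58 in vehicle. DESeq2 called 2, 26, 988, 533, 103 and 188, and its 988 (629 rises) include all 179. With limma-trend the counts were 116 at day 21, 4 in the difference and 95 in vehicle. Without the most abundant sgRNA they were 51 at day 21 (49 rises and 2 falls), 35 in the mean and 3 in the difference. Leaving out 1 library gave 1 to 4 genes at day 14 (1 without vehicle A or B, 2 without pomalidomide A), 24 to 2769 at day 21 (96 without vehicle A, of which 39 are rises, 24 without vehicle B, 1050 without pomalidomide A, 2769 without pomalidomide B), 20 to 1862 in the mean (20 to 26 without a library of day 7 or 14, 38 without vehicle B of day 21, 821 and 1862 without pomalidomide A and B of day 21), 1 to 1307 in the difference and 2 to 28 in vehicle (6 without either baseline, 28 and 2 without vehicle A and B of day 21). At day 7 it gave 0 in edgeR (202 to 368 unadjusted). The remaining library of such a group is assumed to vary like the other groups.

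The rank test called 4 genes at day 7 and 87 at day 14 with percentiles among control sgRNAs, and 3 at day 7 with 2000000 random sets. Sub-library A alone gave 5 at day 14 and 0 at day 21, where the number of random sets keeps even CRBN at adjusted p = 0.0627, and B alone 17 and 4. Lists called in the difference fell from 5 to 3 with an estimated correlation. HELLS reversed to -0.20 in the difference without the most abundant sgRNA. TRAF2 in vehicle, not called at 0.06, turned to -0.10 with control sgRNA scaling and with no replicate block, -0.0231 with its libraries alone and -0.11 with limma-trend, and ranged from -0.61 to 0.58 with 1 library left out. Of 957 values of named genes under other alternatives, 737 kept direction and side of the threshold, 208 lost the call, 7 gained it and 5 reversed; of 620 with 1 library left out these were 378, 235, 5 and 2. The mean log2 ratio of the CRBN sgRNAs was 1.36, 5.24 and 8.16 at days 7, 14 and 21 with a pseudocount of 1 and 1.39, 5.25 and 8.10 with control sgRNA scaling. With all libraries thinned to the shallowest total, edgeR called 166 genes at day 21, 149 of them among the 179.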

Other observations

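The tests of library scaling, of drift shared by vehicle libraries, of the other lists that fell in vehicle, of olfactory receptor genes, of thinning, of label swaps, of shuffled sgRNAs and of resampled members were chosen only after the result was seen; the others were written before it. Beyond the genes described so far, the rank calls of day 14 include some genes picked here after their values were seen, with no test of them as a group: the mitochondrial ribosomal proteins MRPS31 (log2 0.64) and MRPS16 (0.31), the mitochondrial methionyl-tRNA synthetase MARS2 (0.93), the cytochrome oxidase assembly factor PET117 (0.70) and ATP5I, now ATP5ME, a subunit of ATP synthase (1.09). They also hold the mRNA exonuclease XRN1 (1.14), the autophagy enzyme ATG7 (0.75), the N-terminal acetyltransferase NAA10 (0.77), the pyrimidine synthesis enzyme CAD (0.71) and the splicing factor SRSF1 (0.65). Each had 3 or 4 of 6 sgRNAs above the control range, and none was called by edgeR at that day. The m6A RNA methylation genes METTL14 (0.83 ± 0.14) and ALKBH5 (0.60 ± 0.11) stood high at day 14 without a call (adjusted p = 0.165 and 0.274), and at day 21 both rose in edgeR, METTL14 by 0.73 (adjusted p = 0.0418) and ALKBH5 by 0.98 (adjusted p = 0.00321).

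Single sgRNAs also expanded. After scaling for library depth, one sgRNA of ZNF385D in sub-library B had a log2 ratio of pomalidomide over vehicle of 6.28 at day 21, one of RPRML 5.87 and one of EPHA8 6.10, while the other 2 sgRNAs of each gene in B had log2 ratios between -0.49 and 0.27. These genes were picked after their values were seen.

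Ribosomal protein sgRNAs were higher under pomalidomide at days 7 and 14 and lower in vehicle over time. Scaling of the libraries moves all genes alike, so it cannot set the list apart from them. The day 14 median of the list was 0.12, and 0.16 with control sgRNA scaling, while that of all genes was 0.0021 and 0.0473. The list stood above all genes under either scaling, but a factor shared by all genes leaves that gap in place by construction. These values are therefore no separate test of scaling. Fewer divisions under pomalidomide stays open, since the tables go both ways: the 5% of other genes that fell most in vehicle had a day 14 median of 0.18, but DNA replication genes (-0.32 in vehicle) stood at 0.01 (95% interval -0.02 to 0.10) and RNA polymerase II and spliceosome genes (-0.23) at -0.01 (-0.04 to 0.09), with proteasome subunits (-0.27) at 0.07 (0.00 to 0.15). If the shift went in proportion to the fall in vehicle, as in ribosomal proteins, the DNA replication median would be 0.10, and it fell short of that by 0.08 (difference -0.0841, -0.149 to -0.0043), which rests on that assumption and on 1 of 3 lists. Ribosomal proteins themselves stood at 0.05 at day 21. Genes picked in sub-library A and read in B had a day 14 median of 0.0354 (0.0207 to 0.0472), and of 0.0435 (0.0227 to 0.0677) the other way, so chance drift shared by the vehicle libraries cannot be the whole cause of that 0.18, although the smaller value leaves it a part; at day 21 they stood 0.0279 (-0.0034 to 0.0439) and 0.0254 (-0.0017 to 0.0634) above the other genes. That the knockouts themselves protect from the drug stays open and was not tested.

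At day 21, 179 genes passed the threshold, and without the most abundant sgRNA 32 of them did. Chance expansion of single clones may add to them: 1.45% of control sgRNAs of sub-library A rose at least 4-fold (Wilson 95% interval 0.863% to 2.41%), against 1.66% of olfactory receptor sgRNAs, and in B 0.711% against 0.183%. Of olfactory receptor genes 12.1% had a rise at an unadjusted p under 0.05 (45 of 371), against 10.5% of other genes (two-sided Fisher's exact p = 0.305). Most of these rises were not calls, so the rates cannot decide whether loss of the called genes caused most calls. Past the adjusted threshold 3 of 371 olfactory receptor genes and 149 of 18432 other genes rose, counts that were not tested. Thinning left 166 calls, so unequal depth is not needed for most of them. It keeps any noise of the shallow vehicle library in place, so it cannot exclude that library as a source of calls. The tables argue against such expansion for the 11 risen genes with 4 or more sgRNAs above the control range (CRBN, DDB1, COPS2, COPS7A, COPS7B, COPS8, CAND1, EDC4, GNAS, NCOR1 and SPOP), since 1000 shuffles of the sgRNAs within each sub-library gave 0.137 such genes on average and 2 at most. For the other calls it stays open.

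In the mean over days the real labels gave 74 genes. The labels do not say that the days of a sub-library are separate cultures, and with whole sub-libraries swapped there are 2 splits, too few for a share under 0.05 (1 split gave as many genes, the real one; the other gave 1). With the 6 pairs swapped one by one, 32 splits, the highest other gave 33.

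Several genes high at day 14 belong to complexes outside the fixed lists, and 6 such complexes were tested at day 14 on the members not seen before. For m6A the unseen members were all writer genes, since the eraser ALKBH5 had been seen. The median of the unseen members was 0.35 for m6A writers (6 of 6 positive, with 0.12 in sub-library A and 0.63 in B). It was 0.28 for PBAF (5 of 7, with 0.09 and 0.32) and 0.15 for mitochondrial ribosomal proteins (54 of 70). The upper limits from 10000 random gene lists of the same size were 0.154, 0.152 and 0.0485, although resampling the PBAF members gave an interval from -0.03 to 0.38. The medians of the same members were 0.003, -0.0026 and 0.12 at day 7, and 0.57, 0.27 and 0.05 at day 21. At day 14 the median was 0.0623 for N-terminal acetyltransferases (limit 0.152), 0.143 for mRNA decapping (limit 0.149, with DCP2 at 1.16) and -0.0204 for the NCoR complex (limit 0.175), each below its limit. These 3 stay open: resampling the members put their upper bounds at 0.23, 0.32 and 0.33, and against lists matched on the change in vehicle decapping lay at percentile 98.5, above its matched limit of 0.130, with the acetyltransferases at 19.6 and NCoR at 20.8. Growth cost of the knockouts stays open for the first 3 as well. Their medians lay at percentiles 100, 99.9 and 99.9 of lists matched on the change in vehicle, but their resampled lower bounds of 0.15, -0.03 and 0.11 were below the matched limits of 0.163, 0.163 and 0.121, and single-gene changes in vehicle are noisy. A shared effect of these complexes on survival under pomalidomide may be worth a test in other samples.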
